A study of Mus musculus with 10 samples.

How the data were processed

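Liver or liver tumour RNA of 10 male C57BL/6 mice aged 11 months was profiled, 2 libraries each from water-treated wild-type and MLK3-knockout mice and 3 each from wild-type and knockout mice given carcinogen. Per the labels' protocols, treated mice received DEN by intraperitoneal injection at 5 µg per g body weight at 2 weeks of age, and after a lag of 1 week drank water with 0.05% PB until they were killed. The labels give the source of the treated samples as tumour tissue, while the extraction protocol speaks of treated liver; how tumours were separated from the liver around them is not given in the sources used here. Libraries were made, per the labels' protocols, from 50 ng of total RNA with a strand-specific QuantSeq 3' kit (Lexogen, forward version), in which each read starts near the 3' end of a transcript. A count then depends little on transcript length. It does depend on whether the annotated gene contains the true 3' end.

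The authors deposited a single table of whole-number read counts per gene for the 10 samples, not normalized, with versioned Ensembl gene identifiers. Reads were handled with BWA and featureCounts on the mm10 build, per the submitters' processing notes. Versions, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Members of families with near-identical copies, such as the Mup genes, are therefore uncertain one by one, and overlapping or antisense genes may share reads. No molecular identifiers are mentioned, so a count is a number of reads and not of molecules. Columns were assigned to samples by their names, and all per-sample columns were used.

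The table held 39056 genes, of which 21045 had at least 1 count. Symbols came from a table of gene names matched on the identifier without its version, which gave a symbol to 38872 identifiers and none to 184. Positions are those of GENCODE release M21 on GRCm38, the assembly also called mm10. Library totals ran from 12408749 to 18081487 counts, so that 3 counts, used as the limit for a gene without counts as if reads were independent, correspond to 0.156 to 0.231 CPM per library. Replicate libraries were compared for duplicates with a chi-square statistic over genes. Pairs within a group gave 42.6 to 103 per degree of freedom. These values are far from the value near 1 of a library sequenced a second time, or the still lower value of a column deposited a second time. Pairs across groups were not compared.

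Tests were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15811 genes), libraries scaled by TMM, and 1 quasi-likelihood model with a term per group and no covariate was fitted to all 10 libraries, because groups of 2 give little information on spread by themselves. Residual degrees of freedom were 6 and prior degrees of freedom 8.78. The common dispersion was 0.516, a coefficient of variation of 71.8%. The 5 contrasts were WT tumour against WT liver, KO tumour against KO liver, KO against WT liver, KO against WT tumour, and the difference between the first 2 contrasts (the interaction). Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Standard errors were derived from the fold change and its F statistic.

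The 38 gene lists were written before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01 between members, adjusted over the lists of a contrast. Camera was repeated with the correlation estimated from the data, and fry was run as an alternative. Of the lists that camera called with the preset value, 1 of 22 in WT tumours, 0 of 17 in KO tumours against liver, 1 of 16 in KO against WT tumours and 1 of 14 in the interaction held with the estimated correlation. By fry, 17, 0, 10 and 3 of them held, in that order. No list that camera called had a mean, median and test that differed in sign, although this happened among lists that were not called.

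Genes to be named were chosen by a rule fixed in advance. It took for each contrast the 8 largest increases and 8 largest decreases among called genes with at least 10 CPM in the higher group, no overlap between libraries of the groups compared (not asked for the interaction) and a symbol that is not a predicted name. From each list it took up to 3 members with the smallest p among those past the test, or the 2 smallest p as values. Map3k11, Map3k9, Map3k10, Cyp2b10, Cyp2c55, Glul, Axin2, Lgr5, Afp, Gpc3, Mki67 and Top2a were always taken, and so was every called gene of a contrast with 5 or fewer calls.

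The model was tested on simulated counts with 200 genes changed per contrast. They were drawn from a negative binomial distribution with the model's own dispersions, the means over all 10 libraries and the real library sizes. The simulation thus checks the model where its assumptions hold, and not how closely real reads follow them. Among changed genes at 10 CPM or more, an 8-fold change was recovered in 82.9% of cases for WT tumour against liver (14892 genes), 97.4% for KO tumour against liver (14887 genes), 82.9% for KO against WT liver (14867 genes) and 100% for KO against WT tumour (14903 genes). For a 4-fold change these shares were 69.4%, 76.3%, 60% and 75%, and for a 2-fold change 2.78%, 7.14%, 4.88% and 21.2%. Over all changed genes, including those below 10 CPM, an 8-fold change was recovered in 48.4%, 56.5%, 45.6% and 60.4% of cases. A gene that did not pass may therefore still have changed. Unchanged genes made up 1 of 58, 8 of 80, 2 of 53 and 7 of 82 calls, so that the share of false calls could lie somewhat above the nominal 5% in the contrasts of KO tumours.

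Alternatives fixed in advance were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of the compared groups alone, a term for the replicate number, robust dispersions, a test against a fold change of 1.5, and leaving out each library in turn. A filter on a mean of 10 CPM over all libraries was added after the data were examined. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups.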

Results

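Messenger RNA was profiled by 3' tag sequencing in 10 livers or liver tumours of male C57BL/6 mice, either wild-type (WT) or lacking the mixed-lineage kinase MLK3 (KO), a kinase upstream of JNK that is encoded by Map3k11. Tumours had been induced with diethylnitrosamine (DEN), a DNA-alkylating hepatocarcinogen, and promoted with phenobarbital (PB), a drug that activates the nuclear receptor CAR. There were 4 groups: liver of water-treated WT mice (2 libraries), liver of water-treated KO mice (2), tumours of DEN/PB-treated WT mice (3) and tumours of DEN/PB-treated KO mice (3). The series design calls the replicates biological. Total counts were 17694758 and 17442812 in WT liver, 18081487 and 15645620 in KO liver, 16582080, 13555934 and 14200192 in WT tumours and 12408749, 14465995 and 13244775 in KO tumours. Levels below are CPM scaled by TMM factors, with the SD over libraries. Errors of log2 fold changes are standard errors (SE) from edgeR, and adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named. As no molecular identifiers are mentioned in the sources used here, limits drawn from a count of 0, set at 3 counts per library, cover the counting error of independent reads only. Reads of weakly expressed genes came in clumps, genes with a group mean of 10 to 20 counts having none in 21.5% to 30.2% of libraries, so that a count of 0 allows more than 3 reads and the true limits are weaker.

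The targeted gene was measured first. Map3k11 (ENSMUSG00000004054.8, chromosome 19, 5688742 to 5702865, plus strand, GRCm38) stood at 11.4 ± 5 CPM in WT liver (n = 2), 5.59 ± 0.3 in KO liver (n = 2), 12 ± 2.4 in WT tumours (n = 3) and 8.71 ± 2.5 in KO tumours (n = 3). Neither the difference in liver (log2 fold change -1.03, SE 0.58, adjusted p = 0.72) nor that in tumours (-0.46, SE 0.47, adjusted p = 0.77) passed the test. The tags come from the 3' end of the transcript, and the labels do not say which part of the gene was deleted, so this level checks neither the knockout nor the labels. Of its relatives, Map3k10 changed in no comparison that was run and Map3k9 was too low to be tested. None of the 22 tested members of the list of MLK and JNK pathway genes passed edgeR's test in any of the 5 comparisons, over all genes or adjusted over the list alone. DESeq2 did call Mapk3, higher in WT tumours than in WT liver (log2 fold change 0.88; adjusted p = 0.017 in DESeq2 and 0.055 in edgeR), and Mapk8ip1 in the interaction (adjusted p = 0.049 in DESeq2 and 0.34 in edgeR).

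**Figure D1:**
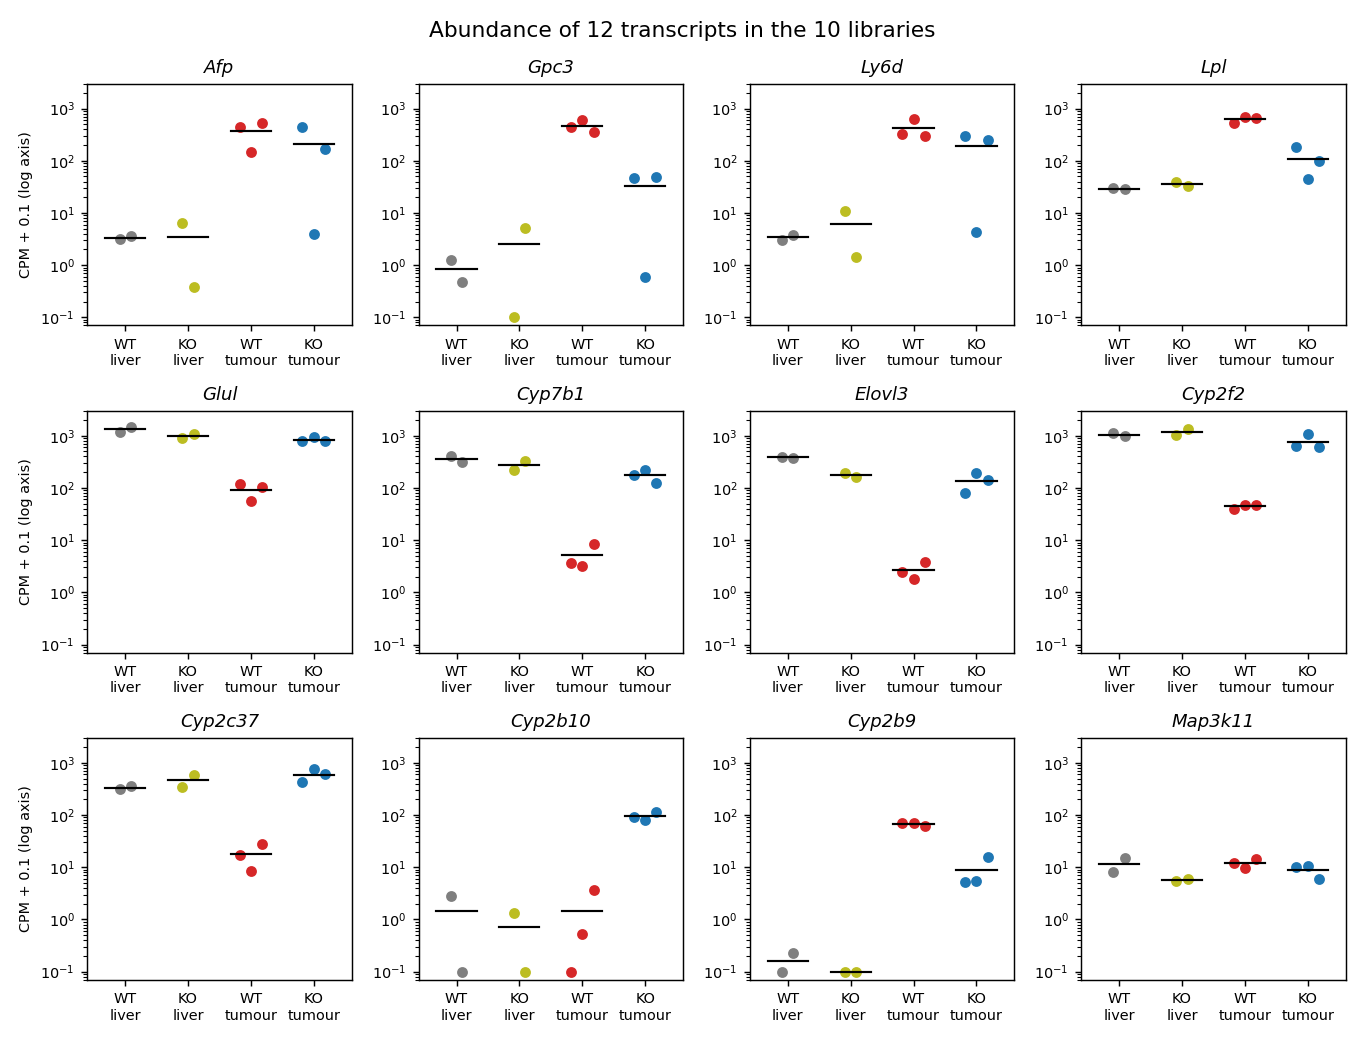
Abundance of 12 transcripts in each of the 10 libraries, as CPM plus 0.1 on a log axis. Points are libraries, placed left to right by replicate number, and bars are group means; Afp, Gpc3 and Ly6d in KO tumour replicate 2 lie near the liver samples, whereas Cyp2b10 is high in all 3 KO tumours.

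WT tumours were compared with WT liver to describe the tumours that form when MLK3 is present. All tumours came from DEN/PB-treated mice and all livers from water-treated mice. A tumour-to-liver change can therefore not be told apart from an effect of the treatment on liver. The same limit holds for the KO mice and for the interaction. Fetal and tumour marker transcripts rose: alpha-fetoprotein (Afp, chromosome 5, 90490737 to 90508907) went from 3.24 ± 0.32 CPM (n = 2) to 377 ± 200 (n = 3), and glypican 3 (Gpc3, chromosome X, 52272426 to 52613950) from 0.755 ± 0.53 to 467 ± 130. Some products of the mature hepatocyte fell, such as glutamine synthetase (Glul, chromosome 1, 153899944 to 153909723), from 1330 ± 240 to 92 ± 33 CPM, and the oxysterol hydroxylase Cyp7b1, from 361 ± 66 to 5.02 ± 2.9 CPM. The major urinary proteins, secreted pheromone carriers made in large amounts by male liver, took 13.8 ± 0.64% of all counts in WT liver and 0.403 ± 0.24% in WT tumours. Albumin went the other way, from 2.13 ± 0.12% to 5.92 ± 0.35% of counts, and the list of secreted liver proteins was mixed, with 7 of 37 higher and 9 lower (7 and 10 adjusted over the list alone; camera adjusted p = 0.043; adjusted p = 0.48 with an estimated correlation). Altogether 575 genes were higher and 743 lower in the tumours among 15811 tested.

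Of 32 tested liver tumour and oncofetal markers, 14 were higher and none lower (17 and 0 adjusted over the list alone), with a median log2 fold change of 3.48, or 3.27 when members at 0 in a group stand at their limit. Besides Gpc3 (log2 fold change 9.26, SE 1.68, adjusted p = 0.0026) and Afp (6.86, SE 1.52, adjusted p = 0.01) these included the netrin receptor relative Igdcc4 (8.58, SE 1.33, adjusted p = 0.00073) and the desaturase Scd2 (7.09, SE 1.06, adjusted p = 0.00052). Cell cycle transcripts moved the same way, 8 of 48 being higher and none lower (11 and 1 adjusted over the list alone). Cyclin D1 (Ccnd1) was 6.76-fold higher, Cdk1 rose from 0.126 to 27.7 ± 4.8 CPM (n = 3), and Top2a was 26.6-fold higher (adjusted p = 0.028), whereas Mki67 missed the threshold (3.82, SE 1.61, adjusted p = 0.18). Among 22 immediate early genes 7 were higher (10 adjusted over the list alone), including the MAPK phosphatases Dusp5 (log2 fold change 7.51) and Dusp6 (1.71) and the transcription factor Maff (3.58). The set test camera called all 3 lists higher (adjusted p = 3.1e-09, 1e-09 and 2.6e-05). These calls were lost with an estimated correlation between members (adjusted p = 0.3, 0.17 and 0.33 with an estimated correlation).

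By the naming rule, Cyp2b9 was also among the genes with the largest increases (959-fold, adjusted p = 7.3e-06). That fold is a fitted value and no limit, as the WT livers had 0 and 2 counts, below 3 counts per library. The largest increases further included the sulfotransferase Sult2a5 (849-fold) and 5 genes without a count in WT liver. Measured against 3 counts per library, and for independent reads only, these were at least 134-fold higher for the protease inhibitor Wfdc12, 123-fold for Psrc1, 90.7-fold for the lipoxygenase Alox5, 57.5-fold for Cd40 and 55.8-fold for Akr1b7. Wfdc12 varied widely between the WT tumours, with 236, 852 and 25 counts.

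Transcripts of both lobular zones fell. Wnt target and pericentral genes were lower in 14 of 28 cases and higher in none (18 and 0 adjusted over the list alone), as for Glul (log2 fold change -3.85, SE 0.29, adjusted p = 9.4e-07), ornithine aminotransferase Oat (-4.91, SE 0.46) and Axin2 (-4.67, SE 1.3, adjusted p = 0.037), a feedback inhibitor of Wnt signalling. Lgr5 did not pass (-0.12, SE 0.68, adjusted p = 0.96). Periportal genes were lower in 11 of 24 cases and higher in 3 (13 and 3 adjusted over the list alone), led by Cyp2f2 (-4.54, SE 0.28, adjusted p = 1.3e-07), Igf1 (-2.61) and Etnppl (-5.98). Bile acid genes fell in 16 of 25 cases and rose in 2 (16 and 5 adjusted over the list alone), including the uptake carrier Slco1b2 (13.9-fold lower) and Cyp27a1 (7.31-fold lower). Camera gave adjusted p = 1.1e-10, 9.6e-05 and 4.8e-07 for these lists, and adjusted p = 0.17, 0.3 and 0.27 with an estimated correlation.

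Sex-biased liver genes changed as well. Of 24 male-biased genes 18 fell and none rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -3.55. The fatty acid elongase Elovl3 fell from 383 ± 11 to 2.56 ± 1 CPM, the hydroxylase Cyp4a12b from 109 ± 16 to 1.21 ± 0.71 CPM, and Mup21 was 32.9-fold lower. Camera called this list at adjusted p = 2.3e-22, and it was the only list in this comparison whose call held with an estimated correlation (adjusted p = 0.0073 with an estimated correlation). Female-biased genes were higher in 6 of 29 cases and lower in 4, with the same numbers adjusted over the list alone. Among them Cyp2a4 rose from 33.2 ± 13 to 1910 ± 330 CPM and lipoprotein lipase (Lpl) from 29.2 ± 0.86 to 619 ± 73 CPM (camera adjusted p = 0.047; adjusted p = 0.3 with an estimated correlation). Reads of the near-identical Mup genes can be assigned to the wrong member, so the family share stated above is firmer than the values of Mup7 (686-fold lower), Mup11 (384-fold) or Mup1 (363-fold).

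Targets of PB and CAR did not behave alike. Of 37 tested, 4 were higher and 13 lower (7 and 16 adjusted over the list alone; camera adjusted p = 0.00074; adjusted p = 0.4 with an estimated correlation). Cyp2b9, which is also female-biased, rose to 68.2 ± 4.8 CPM, while Cyp2c37 was 18.7-fold lower and the retinaldehyde dehydrogenase Aldh1a1 10.8-fold lower. The best-known mouse target of PB, Cyp2b10 (chromosome 7, 25897620 to 25926624), stood at 1.35 ± 1.9 CPM in WT liver and 1.34 ± 2 in WT tumours (log2 fold change -0.03, SE 1.23, adjusted p = 1), and Cyp2c55 did not pass either (-0.46, SE 1.77, adjusted p = 0.93).

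Energy metabolism and lipid genes were lower in part. Respiratory chain subunits fell in 11 of 32 cases (22 adjusted over the list alone), by a median of -0.69 on the log2 scale, and mitochondrially encoded transcripts fell in 6 of 13 (10 adjusted over the list alone). Mitochondrial transcripts made up 4.69 ± 0.58% of counts in WT tumours (n = 3) against 7.42 ± 0.21% in WT liver (n = 2). Genes of fatty acid oxidation were lower in 13 of 31 cases and higher in 2 (15 and 4 adjusted over the list alone), and cholesterol synthesis genes were lower in 9 of 25 (12 adjusted over the list alone), with Pmvk 2.59-fold and Ebp 2.47-fold lower. Camera called these 4 lists lower (adjusted p = 1.5e-09, 2.3e-05, 0.00055 and 0.0011). None of the 4 calls held (adjusted p = 0.17, 0.3, 0.4 and 0.35 with an estimated correlation).

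Markers of some other cell types differed as well. Macrophage and Kupffer cell genes were higher in 10 of 33 cases and lower in 1 (14 and 3 adjusted over the list alone): the class II gene H2-Aa was 4.36-fold and Cd5l 2.83-fold higher, but the scavenger receptor Cd163 was 24.2-fold lower. Cholangiocyte genes rose in 7 of 21 cases (8 adjusted over the list alone), with Tstd1 going from 32.8 ± 14 to 830 ± 160 CPM and Tspan8 from 1.83 ± 0.26 to 169 ± 110. Interferon response genes rose in 7 of 43 (12 adjusted over the list alone), with Ifi44 35.8-fold higher. Camera gave adjusted p = 3.7e-05, 3.6e-05 and 2.8e-05 for the 3 lists, and adjusted p = 0.35, 0.2 and 0.26 with an estimated correlation. T and NK cell genes had 1 of 29 members higher, Ccl5 (camera adjusted p = 0.013; adjusted p = 0.48 with an estimated correlation). B and plasma cell genes (1 of 25 higher, Ly6d, which was also on the list of tumour markers), neutrophil genes (0 of 13 higher and 1 lower, G0s2, an inhibitor of fat breakdown), endothelial genes (1 of 33, Esm1), red blood cell genes (2 of 9, both beta-globins) and stellate cell and matrix genes (4 of 43 higher, 2 lower) held few called members. The list of pancreas, fat and muscle genes had 1 of 8 members past the test, Car3, which liver also expresses and which was 72.6-fold lower.

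DESeq2 called 1274 genes higher and 1110 lower in this comparison, and 1316 of the 1318 genes called by edgeR were among them. The number called higher dropped to 378 without WT liver replicate 1 and to 365 without WT tumour replicate 2.

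KO tumours were compared with KO liver in the same way. Only 12 genes passed, all higher in the tumours, and the 7 taken by the naming rules covered different functions. Cyp2b9 had no count in KO liver and stood at 8.61 ± 5.8 CPM in KO tumours (n = 3), at least 44.8-fold higher if reads were independent (adjusted p = 0.0068). The apolipoprotein Apoa4 rose from 35.2 ± 0.12 to 511 ± 410 CPM (adjusted p = 0.045), the antimicrobial peptide Leap2 from 106 ± 28 to 873 ± 350 (adjusted p = 0.021), Ipcef1 from 0.0354 to 12.1 ± 9.8 and the centrosomal gene Cep170 from 0.249 ± 0.052 to 10.1 ± 5.8. Dennd4a (log2 fold change 4.12, SE 0.62) and the mitochondrial import gene Timm22 (4.66, SE 0.69) had the same adjusted p of 0.021. The counts of these 2 genes ordered the 10 libraries almost alike, and the count table does not show whether the reads come from their transcripts or from a repeat or another transcript.

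The tumour markers were uneven among the KO tumours. Afp stood at 206 ± 220 CPM (n = 3) against 3.32 ± 4.3 in KO liver (n = 2), a log2 fold change of 5.92 (SE 1.46) that did not pass (adjusted p = 0.15), with 5791, 55 and 2337 counts in replicates 1, 2 and 3. Gpc3 behaved likewise (608, 7 and 678 counts; 3.74, SE 1.3, adjusted p = 0.34). Cyp2b10 had 1184, 1165 and 1589 counts in the 3 KO tumours and 22 and 0 in the KO livers (7.16, SE 1.5, adjusted p = 0.1). Glul was similar in KO tumours and liver (832 ± 87 against 997 ± 130 CPM; -0.26, SE 0.28, adjusted p = 0.82), as were Axin2 (0.31, SE 1.21) and Lgr5 (0.05, SE 0.67).

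No list had more than 1 member past the test over all genes. Adjusted over the list alone, 15 of 32 oncofetal markers were higher in KO tumours than in KO liver, as were 5 of 37 CAR targets, 4 of 28 p53 targets and 4 of 29 female-biased genes. Camera called 10 lists higher, including oncofetal markers (adjusted p = 0.001) and macrophage genes (adjusted p = 0.00061), and 7 lower, including cholesterol synthesis (adjusted p = 0.00017) and secreted liver proteins (adjusted p = 0.0003). None of these calls held with an estimated correlation (adjusted p = 0.62 with an estimated correlation for each of the 4). For fatty acid oxidation genes, called lower, the median was -0.36 (adjusted p = 0.0054; adjusted p = 0.62 with an estimated correlation). T and NK cell genes had a fitted median of 3.71, which became 1.2 when members at 0 in a group stood at their limit.

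An unadjusted p under 0.05 was reached by 1520 genes, where 791 would be reached by chance, and DESeq2 called 385 genes higher and 42 lower. A fit of the compared groups alone called none. Of the 12 genes 1 stayed called among genes with a mean of 10 CPM or more, a filter chosen after the data were examined. That filter removed Cep170 before any test, so the number does not show how many genes failed a retest. Without either KO liver replicate 14 genes were called, of which 4 were among the 12. Without KO tumour replicate 2, whose Afp and Gpc3 counts were those of liver, 189 genes were higher and 13 lower; the count of higher genes was 52 and 48 without WT liver replicates 1 and 2, 6 and 7 without WT tumour replicates 1 and 2, and 3 without KO tumour replicate 1 or 3.

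KO and WT liver of water-treated mice were compared to find effects of the genotype without the carcinogen. A single gene passed: Fam102b, with 84 and 54 counts in WT liver and none in KO liver, was at least 22.6-fold lower if reads were independent (adjusted p = 0.047). Its call ended in a fit of the compared groups alone and in a test against a fold change of 1.5. A filter on a mean of 10 CPM, chosen after the data were examined, removed the gene before any test and does not bear on the call. None of the 38 lists passed camera. The scavenger receptor Marco stood at 4.47 ± 1.1 CPM in WT liver (n = 2) and 54.9 ± 11 in KO liver (n = 2), a log2 fold change of 3.62 (SE 0.61) that missed the threshold (adjusted p = 0.12). Clock genes came nearest as a list (camera adjusted p = 0.16), with 5 members higher and 2 lower adjusted over the list alone. Per3 stood at 6.21 ± 3.4 CPM in WT and 30.7 ± 5.8 in KO liver (2.3, SE 0.43, adjusted p = 0.16), and Tef had a log2 fold change of 1.7 (SE 0.34, adjusted p = 0.22). Cyp2b10 (-1.02, SE 1.44), Glul (-0.42, SE 0.31) and Elovl3 (-1.13, SE 0.36, adjusted p = 0.55) did not pass.

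Beside this single call, 1151 genes had an unadjusted p under 0.05 (791 by chance), and DESeq2 called 89 genes higher and 113 lower. No gene was called lower when KO liver replicate 1 or any of the 6 tumour libraries was left out, and 6, 4 and 2 genes were lower without WT liver replicate 1, WT liver replicate 2 and KO liver replicate 2. Fam102b stayed called without either WT liver replicate and was not among the 2 genes called without KO liver replicate 2.

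The comparison of KO with WT tumours addressed which tumour transcripts differ with the genotype. Some liver transcripts that were low in WT tumours were far higher in the KO tumours: Glul stood at 832 ± 87 CPM (n = 3) against 92 ± 33 (n = 3), Cyp7b1 at 174 ± 45 against 5.02 ± 2.9, and Elovl3 at 138 ± 56 against 2.56 ± 1. Tumour-associated transcripts were lower, Gpc3 standing at 32.1 ± 27 CPM against 467 ± 130 and Lpl at 110 ± 70 against 619 ± 73. The Mup family took 8.21 ± 1.7% of counts in KO tumours and 0.403 ± 0.24% in WT tumours, and albumin took 2.4 ± 0.32% and 5.92 ± 0.35%. Secreted liver proteins showed no common direction, with 7 of 37 higher and 7 lower (11 and 8 adjusted over the list alone; median 0.07; camera adjusted p = 0.72). In all, 514 genes were higher and 201 lower in KO tumours.

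CAR targets were higher in 15 of 37 cases and lower in 1 (17 and 3 adjusted over the list alone; camera adjusted p = 4.9e-07; adjusted p = 0.32 with an estimated correlation). Cyp2b10 stood at 95.7 ± 17 CPM in KO tumours and 1.34 ± 2 in WT tumours (log2 fold change 6.17, SE 1.17, adjusted p = 0.0054). Cyp2c54 (5.79, SE 0.62, adjusted p = 3.6e-05), Cyp2c37 (5.06, SE 0.41, adjusted p = 2.4e-06) and Cyp2c29 (3.9, SE 0.36, adjusted p = 1e-05) were higher too. Cyp2b9 went the other way, at 8.61 ± 5.8 CPM in KO tumours and 68.2 ± 4.8 in WT tumours (-2.98, SE 0.46, adjusted p = 0.0013).

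Of 24 male-biased genes 17 were higher and none lower (19 and 0 adjusted over the list alone), with a median log2 fold change of 3.61. Mup21 (5.22, SE 0.28, adjusted p = 9e-08), Cyp4a12b (5.69, SE 0.38, adjusted p = 3.3e-07) and Elovl3 (5.74, SE 0.37, adjusted p = 3.3e-07) led it. Camera called the list at adjusted p = 6e-25, and the call held (adjusted p = 0.0053 with an estimated correlation). Wnt target and pericentral genes were higher in 13 of 28 cases and lower in none (16 and 0 adjusted over the list alone), with Oat 16.5-fold and Cyp27a1 5.83-fold higher. Periportal genes were higher in 9 of 24 cases and lower in 2 (10 and 3 adjusted over the list alone), with Cyp2f2 17.3-fold and Igf1 5.57-fold higher. Bile acid genes were higher in 14 of 25 cases (16 higher and 1 lower adjusted over the list alone), among them Slco1b2 (13.9-fold). For these 3 lists camera gave adjusted p = 4.5e-12, 0.0002 and 1.1e-07, and adjusted p = 0.15, 0.32 and 0.25 with an estimated correlation. Axin2 (3.02, SE 1.18, adjusted p = 0.22) and Lgr5 (1.14, SE 0.61, adjusted p = 0.41) did not pass.

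Metabolic genes differed in part. Respiratory chain subunits were higher in 10 of 32 cases (21 adjusted over the list alone) and mitochondrially encoded transcripts in 5 of 13 (9 adjusted over the list alone), both by small amounts, such as 1.87-fold for Ndufb5 and 1.81-fold for mt-Co3. Fatty acid oxidation genes were higher in 8 of 31 cases and lower in 1 (14 and 4 adjusted over the list alone), and fatty acid synthesis genes in 5 of 24 and lower in 1 (11 and 1 adjusted over the list alone). In the latter list Thrsp, a lipogenic regulator, was 15.8-fold and fatty acid synthase (Fasn) 2.55-fold higher. Camera called these 4 lists higher (adjusted p = 1.8e-10, 2.1e-05, 0.0025 and 0.014), and all 4 calls were lost with an estimated correlation (adjusted p = 0.15, 0.32, 0.56 and 0.32 with an estimated correlation). Of 25 cholesterol synthesis genes, 9 were lower in WT tumours than in WT liver. Between the tumours, 3 of 25 were higher in KO (5 higher and 1 lower adjusted over the list alone), at a median of 0.08 (camera adjusted p = 0.52). Among glycolysis and hypoxia genes 0 of 27 passed (2 higher adjusted over the list alone, camera adjusted p = 0.76).

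Oncofetal markers were lower in KO tumours in 6 of 32 cases and higher in none (8 and 0 adjusted over the list alone), including Igdcc4 (log2 fold change -3.54, SE 0.8), Gpc3 (-3.86, SE 1.04, adjusted p = 0.048), Krt18 (-0.99, SE 0.2) and Sox9 (-1.12, SE 0.23). Afp did not pass (-0.87, SE 0.97, adjusted p = 0.81). Cholangiocyte genes were lower in 5 of 21 cases (6 adjusted over the list alone), immediate early genes in 3 of 22 (5 adjusted over the list alone; Maff, Ccn2 and Dusp6), and genes of the unfolded protein and amino acid stress response in 3 of 31 (4 adjusted over the list alone), where the pseudokinase Trib3 was 7.3-fold lower. Cell cycle genes had 1 of 48 members past the test, Stmn1 (2.83-fold lower; 1 adjusted over the list alone), at a list median of -1.42. Mki67 (-2.12, adjusted p = 0.48) and Top2a (-1.28, SE 0.89, adjusted p = 0.58) did not pass. Camera called these 5 lists lower (adjusted p = 2.2e-07, 0.00011, 2.1e-05, 2.3e-06 and 3e-07). The calls were lost in each case (adjusted p = 0.32, 0.25, 0.32, 0.33 and 0.25 with an estimated correlation). Camera also called p53 targets and ribosomal proteins lower (adjusted p = 0.0013 and 0.0063; adjusted p = 0.29 and 0.74 with an estimated correlation), although 0 of 28 and 0 of 45 members passed, over all genes or adjusted over the list alone.

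Outside the lists, the largest decreases in KO tumours by the naming rule were those of the secreted Wfdc12 (89.6-fold) and Wfdc15b (17.2-fold), the trypsin inhibitor Spink1 (16.8-fold), the macrophage glycoprotein Gpnmb (21-fold), Bex1 (20.1-fold), Nipal1 (17.4-fold) and the folate enzyme Mthfd1l (15.2-fold). The largest increases were those of 7 Mup genes and pseudogenes, from 117-fold for Mup15 to 266-fold for Mup7, and of dopachrome tautomerase (Dct), with 173, 255 and 151 counts in KO tumours and 1, 0 and 1 in WT tumours. Among macrophage genes, Marco (7.09-fold) and Cd163 (22.9-fold) were higher and Gpnmb lower, and no more of the 33 passed (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.11).

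KO tumour replicate 2 stood apart from the other KO tumours on the first principal component (-47 against 26.5 and 13.5), towards the livers (-82.4 to -73.9) and away from the WT tumours (103.2 to 112.3). The number of genes called lower in KO tumours depended on single libraries: 114 and 110 without KO tumour replicates 2 and 3, 91 and 122 without WT tumour replicates 2 and 3. The counts of genes called higher lay between 345 and 547 with any 1 library left out.

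**Figure D2:**
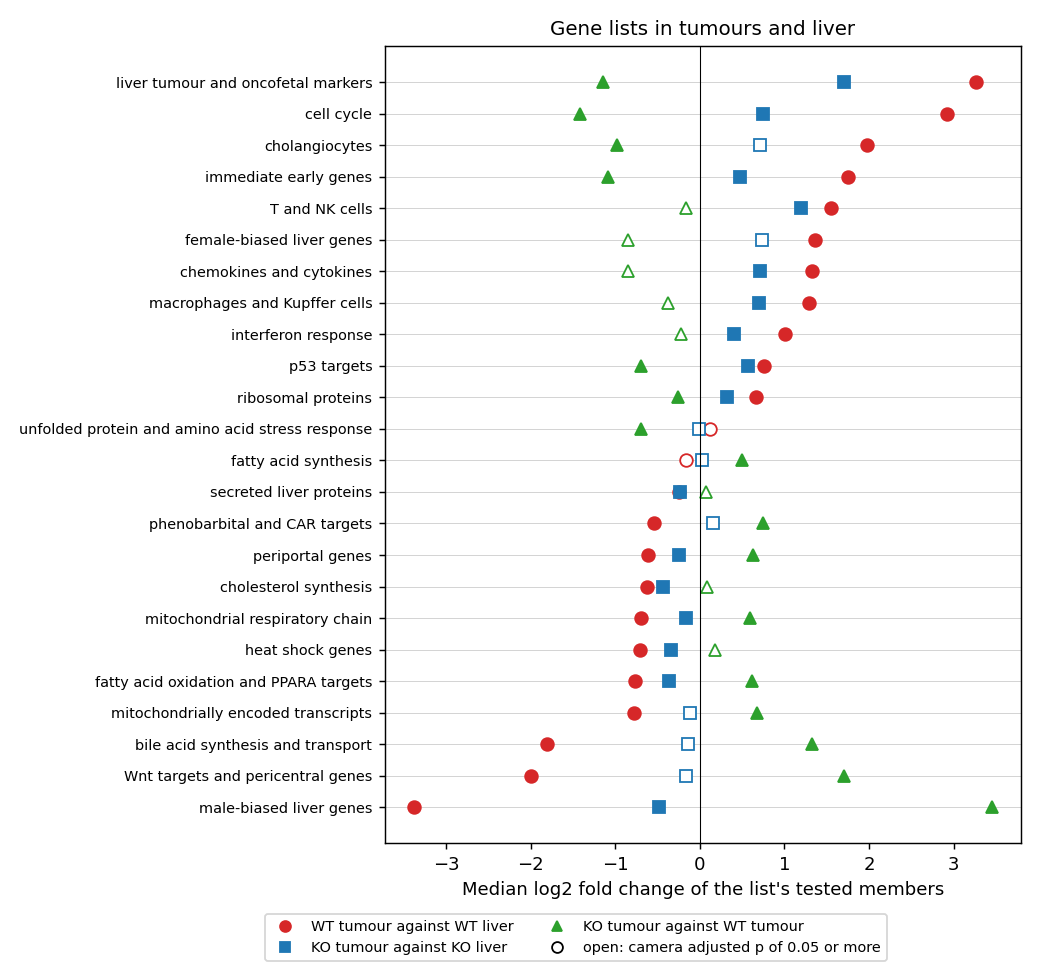
Median log2 fold change of the tested members of 24 lists that camera called in WT tumours against WT liver or in KO against WT tumours, with members at 0 in a group placed at their limit. Circles, squares and triangles stand for WT tumour against WT liver, KO tumour against KO liver and KO against WT tumour, and filled symbols for a camera adjusted p under 0.05; most lists lie nearer to 0 in KO than in WT tumours, as for male-biased genes (-3.38 and -0.48).

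The interaction of genotype and tumour asked directly whether the tumour-to-liver change differed between KO and WT. For 193 genes the log2 change was larger (or less negative) in KO and for 58 it was smaller (or more negative). Larger and smaller changes in the interaction refer to this signed value throughout, and not to the size of the response. Of the male-biased genes, 14 of 24 had a larger change (19 adjusted over the list alone; camera adjusted p = 9.1e-21; adjusted p = 0.0089 with an estimated correlation), for example Elovl3 (interaction log2 6.87, SE 0.53, adjusted p = 6.7e-06) and Cyp4a12b (6.35, SE 0.53, adjusted p = 1.1e-05). CAR targets and Wnt target and pericentral genes had 9 such members each (15 and 14 adjusted over the lists alone), including Cyp2c54 (5.92, SE 0.86, adjusted p = 0.0019) and Glul (3.59, SE 0.41, adjusted p = 0.0002). Camera called both lists (adjusted p = 0.00026 and 7.4e-09), which did not hold (adjusted p = 0.71 and 0.44 with an estimated correlation). Bile acid genes had 6 (14 adjusted over the list alone), among them Cyp7b1 (5.51, SE 0.54). Changes smaller in KO included those of Lpl (-2.78, SE 0.56, adjusted p = 0.018), Cyp2a4 (-3.82, SE 0.75, adjusted p = 0.016), Trib3 (-3.05, SE 0.68) and Tstd1 (-2.94, SE 0.67). The interaction did not pass for Cyp2b10 (7.18, SE 1.83, adjusted p = 0.07), Gpc3 (-5.52, SE 1.83, adjusted p = 0.19) or Afp (-0.94, SE 1.65, adjusted p = 0.91). DESeq2 called 465 and 262 genes, and the 58 became 33 without KO liver replicate 2 or KO tumour replicate 3 and 31 and 34 without WT tumour replicates 2 and 3.

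**Figure D3:**
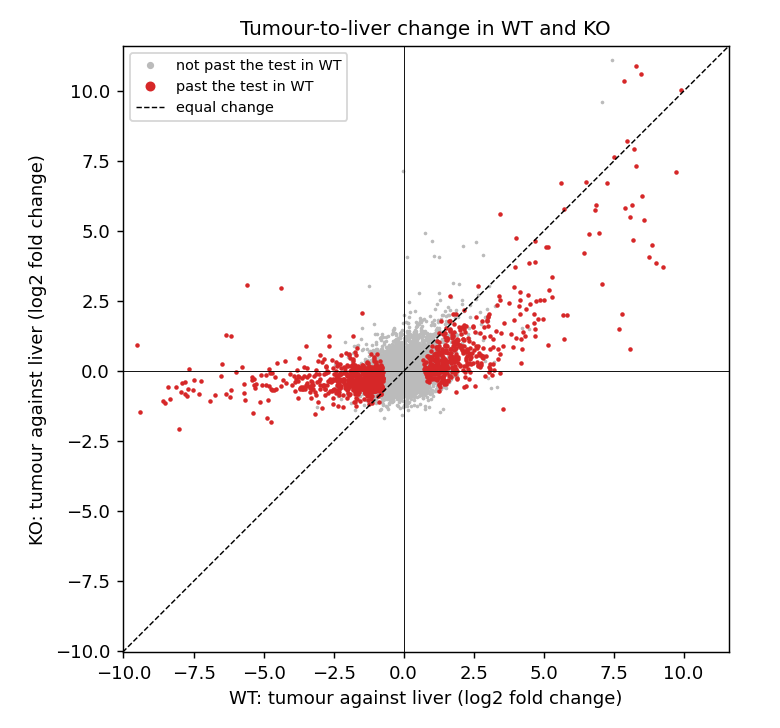
Tumour-to-liver log2 fold change of 7636 genes with a mean of 10 CPM or more, in WT mice (horizontal) and KO mice (vertical), fitted from different libraries. Red points passed the test in WT, and most lie between the horizontal axis and the dashed line of equal change.

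The 2 tumour-to-liver contrasts share no libraries. Across the 15811 genes their log2 fold changes had a Pearson correlation of 0.225 and a Spearman correlation of 0.238. For the 7636 genes with a mean of 10 CPM or more, a filter chosen after the data were examined, the values were 0.55 and 0.396. Genes are not independent replicates, so these values describe the genes only. Of the 575 genes higher in WT tumours, 82.6% had a positive change in KO, with a median of 0.66 against 2.27 in WT. Of the 743 lower in WT tumours, 78.6% had a negative change in KO, with a median of -0.31 against -1.64. Picking genes by the WT test inflates their WT medians. Within single KO tumours, the median change of the higher genes was 0.92, 0.13 and 0.82 in replicates 1, 2 and 3, and that of the lower genes -0.52, -0.06 and -0.41.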

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

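The split of the 6 tumour libraries and the test of non-tumour liver by a sum of shares were written down before their results were seen, and the tests of water-type liver, of KO tumour replicate 2 and of the Cyp2b genes were chosen after the result was seen.

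The tumour-to-liver change differed between KO and WT mice for 251 genes by the interaction test. The signed log2 change was larger (or less negative) in KO for 193 and smaller (or more negative) for 58. A fall in WT that was weak in KO therefore counts as larger, as for Cyp7b1 (-6.17 in WT and -0.65 in KO). Among male-biased genes, the interaction log2 was 6.87 for Elovl3, 6.35 for Cyp4a12b, 5.51 for Cyp7b1, 4.55 for Mup21 and 3.11 for C6, and for Car3, listed with fat and muscle genes, 5.25. Secreted liver proteins, to which C6 and Mbl1 (1.86) belong, had 3 of 37 larger and 5 smaller changes (8 and 8 adjusted over the list alone; camera adjusted p = 0.88). It was 3.59 for Glul, 4.41 for Oat and 3.55 for Rgn among pericentral genes, and 3.91 for Cyp2f2, 5.95 for Etnppl and 2.34 for Igf1 among periportal ones. For CAR targets it was 5.92 for Cyp2c54, 4.59 for Cyp2c37 and 3.91 for Cyp2c29, for bile acid carriers 3.84 for Slco1b2 and 3.17 for Slc10a1, and for the glutathione transferase Gsta3 1.7. Lipid genes gave 4.63 for Fitm1, 3.41 for Thrsp, 2.96 for G0s2 and 2.27 for Plin5. The near-identical Mup genes gave 7.82 for Mup10, 7.95 for Mup7, 7.75 for Mup22 and 10.4 for Mup-ps2, the last a fitted value that is no limit because WT tumours had no count. Further positive values were those of Dct (7.74), Pitx3 (7.96), Nat8f5 (8.27) and the clock gene Nfil3 (3.03). The acute phase genes Saa1 (7.34) and Saa2 (8.65) varied within groups, Saa1 having 29864 and 7245 counts in WT liver and 35053, 941 and 4270 in KO tumours.

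Smaller changes in KO passed the same test for Lpl (-2.78), Cyp2a4 (-3.82), Trib3 (-3.05), Il1rn (-3.18), Tstd1 (-2.94), Atp1b1 (-1.75), Krt18 (-1.37), Apoa1 (-1.79), Vnn1 (-2.71), Mthfd1l (-7.3) and the clock gene Per3 (-2.98). For another 7 genes the counts in WT liver were between 0 and 16 while those in KO liver were between 13 and 242: Hbegf (-8.92), Btc (-7.18), Krt23 (-9.43), Npdc1 (-7.24), Bmp7 (-6.71), Nckap1l (-5.31) and Pnpla3 (-7.84). Their interaction therefore rests on low counts in WT liver as well as on the tumours. A difference between the livers also entered the interaction of the clock genes Per3 and Nfil3, with log2 fold changes of 2.3 and -1.46 in KO against WT liver and -0.68 and 1.57 in KO against WT tumours, none of which passed, and of Vnn1 (1.47 and -1.25, neither of which passed).

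At the level of lists, the median interaction log2 was 3.33 for male-biased genes, 1.78 for Wnt target and pericentral genes, 1.56 for bile acid genes, 0.95 for CAR targets, 0.73 for mitochondrially encoded transcripts, 0.51 for the respiratory chain and 0.38 for periportal genes. It was -1.75 for cell cycle genes, -0.98 for cholangiocyte genes, -0.94 for oncofetal markers, -0.81 for immediate early genes, -0.52 for interferon response genes, -0.29 for ribosomal proteins and -0.16 for the unfolded protein and amino acid stress response. With an estimated correlation between members, the call held for the male-biased genes (adjusted p = 0.0089 with an estimated correlation) and for no other list.

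Much of this follows a single pattern, in which KO tumours lay between liver and WT tumours. A mixture of tissue like the water-treated liver with tissue like the WT tumours is argued against by Cyp2b10. It was 22.6-fold higher in the lowest KO tumour library than in the highest of the 7 other libraries. This does not bear on water-type liver mixed with tumours that themselves express Cyp2b10. KO tumour replicate 2 is not the whole cause, since 62.4% of the 715 genes called between KO and WT tumours stayed called without it. Liver of carcinogen-treated mice that is not tumour remains open. It was checked over called genes with at least 10 CPM in a group, 158 at least 8-fold higher and 112 at least 8-fold lower in WT tumours. Mup genes were left out of the lower set. Picking genes by the WT test inflates the WT tumour level of the higher ones. The KO liver was that of water-treated mice, so the check covers treated liver only as far as these genes have like levels in both. In a mixture, the median share of the WT tumour level and that of the KO liver level should add up to 1. They added up to 0.985, 1.02 and 0.959 in replicates 1, 2 and 3 (95% bootstrap intervals over genes 0.902 to 1.07, 0.964 to 1.11 and 0.889 to 1.05). The intervals treat genes as independent and the WT tumour and KO liver levels as fixed. Differences between animals are thus left out, and the true uncertainty is wider. Halving each log2 change would give 0.422. That is a single alternative, and uneven changes within the tumours could also add up to near 1, so the sums do not decide between these. Replicate 2 was near liver in both shares (0.0615 and 0.959), so its sum would be near 1 under any explanation and separates none. A candidate explanation is that tissue like the WT tumours made up only part of these samples (0.322, 0.0615 and 0.286 by the higher genes, with interquartile ranges from 0.0157 to 0.528). An effect of MLK3 on transcription within the tumours stays open too, as no treated liver without tumour was analysed here, and with 10 splits of the 6 tumour libraries chance cannot be brought under a share of 0.05 (1 split, the real one, gave 715 genes, and the highest other gave 1).

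Cyp2b10 and Cyp2b9, both on chromosome 7, moved in opposite directions: the WT tumours had 0, 6 and 56 counts of Cyp2b10 and 1367, 971 and 976 of Cyp2b9, and the KO tumours 1184, 1165 and 1589 of Cyp2b10 and 66, 78 and 212 of Cyp2b9. Reads shared fully between these paralogs would keep their ratio alike, yet it differed 128-fold between the lowest KO and the highest WT tumour. A partial assignment of reads to the wrong paralog is not excluded by this ratio. Together the 2 genes had 1367, 977 and 1032 counts in the WT tumours and 1250, 1243 and 1801 in the KO tumours. In the livers their sum was 0 to 43 counts. Whether the WT mice lacked PB when sampled cannot be told apart from a loss of the response inside their tumours, because 4 of the 37 CAR targets were higher in WT tumours than in WT liver and 13 were lower. The difference in genotype stays open and untested as a cause. KO tumour replicate 2 had 1165 counts of Cyp2b10 although it had 55 counts of Afp and 7 of Gpc3, within the range of the livers (4 to 111 and 0 to 70), so that Cyp2b10 did not follow these 2 genes there.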

How the results depend on the processing

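The filter on a mean of 10 CPM was chosen after the data were examined, and all other alternatives before. Of 517 values for named genes, 248 were past the test. The 517 had 9059 values under alternatives, where a gene left out by a filter or without an adjusted p gave none. Of these, 8305 lay on the same side of the threshold, 419 were no longer past it and 335 newly past it. No called value had the opposite sign. Under every alternative in which they were tested, 147 of the 248 passed. Of 69 list calls, the estimated correlation ended 66 and fry 39, none reversed, and 3 passed under every alternative, those of the male-biased genes. Without a filter on low counts, 925 genes were higher in WT tumours than in liver, 342 higher and 44 lower in KO tumours than in liver, 39 higher and 72 lower in KO than in WT liver, 435 lower in KO than in WT tumours, and 432 and 203 had a larger or smaller change in the interaction. DESeq2 gave 1274 higher in WT tumours, 385 and 42 in KO tumours, 89 and 113 in KO liver, 826 and 394 in KO against WT tumours, and 465 and 262 in the interaction. Testing against a fold change of 1.5 left 321 higher and 414 lower in WT tumours, 0 lower in KO liver, 267 and 68 in KO against WT tumours and 22 with a smaller change. A fit of the compared groups alone gave 0 genes higher in KO tumours than in liver and 0 lower in KO liver. The 10 CPM filter gave 1 and 0 for these results. The Pearson correlation of tumour effects was 0.143 in a refit without a filter and 0.552 in a refit with that of 10 CPM. The filters change the genes tested; for the other alternatives the cause was not tested.

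Leaving out 1 library at a time gave 365 to 710 higher and 505 to 807 lower genes in WT tumours, 3 to 189 higher and 0 to 13 lower in KO tumours against liver, 0 to 3 higher and 0 to 6 lower in KO liver, 345 to 547 higher and 91 to 269 lower in KO against WT tumours, 138 to 215 larger and 31 to 72 smaller changes in the interaction, and correlations of tumour effects from 0.168 to 0.243. Counts moved by more than 1.5-fold for genes higher in WT tumours without WT tumour replicate 2 (365) or WT liver replicate 1 (378). For genes higher in KO tumours against liver they did so without KO tumour replicates 1, 2 or 3 (3, 189 and 3), WT liver replicates 1 or 2 (52 and 48) and WT tumour replicates 1 or 2 (6 and 7). For genes lower in KO against WT tumours this was seen without WT tumour replicates 2 or 3 (91 and 122) and KO tumour replicates 2 or 3 (114 and 110), and for smaller changes in the interaction without WT tumour replicates 2 or 3 (31 and 34), KO liver replicate 2 (33) and KO tumour replicate 3 (33). Of all main calls, 1 had the opposite sign in a refit, in WT tumours without WT liver replicate 2.

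Equal replicate numbers did not mark pairs: correlations of deviations over 13 same-number pairs ran from -0.006 to 0.024. With the replicate number as a block, 455 genes were higher and 620 lower in WT tumours, 11 higher in KO tumours against liver, 1 higher and 0 lower in KO liver, 491 and 190 in KO against WT tumours, and 203 and 52 in the interaction.

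In WT liver 3 counts correspond to 0.189 CPM, a limit for independent reads, which those of weakly expressed genes were not.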

Other observations

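All tests of clumped reads were chosen after the result was seen, and the values of lists come from tests fixed beforehand.

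Further lists of stress, translation and inflammation genes were tested in WT tumours against WT liver. Acute phase genes were higher in 4 of 32 cases and lower in 6 (6 and 8 adjusted over the list alone), where the interleukin-1 antagonist Il1rn was 25.6-fold, Apcs 4.82-fold and the copper carrier Cp 2.95-fold higher. NRF2 targets were higher in 7 of 32 cases, such as Srxn1 (6.16-fold), and lower in 4, such as catalase (Cat, 3.19-fold; 10 and 5 adjusted over the list alone), and lipid droplet genes rose in 4 of 19 and fell in 4 (5 and 5 adjusted over the list alone), with Lpl among the former and Plin5 (6.17-fold) and Fitm1 (26.1-fold) among the latter. Of 28 p53 targets 3 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0067; adjusted p = 0.3 with an estimated correlation), and of 19 heat shock genes 4 fell, as Fkbp4 did by 2.43-fold (8 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.49 with an estimated correlation). Ribosomal protein genes had 2 of 45 members higher (6 adjusted over the list alone), at a median of 0.66 (camera adjusted p = 4.4e-06; adjusted p = 0.4 with an estimated correlation). Genes of the unfolded protein and amino acid stress response were higher in 2 of 31 cases, Psat1 (0.22 ± 0.13 CPM in WT liver and 62.5 ± 16 in WT tumours) and Trib3 (18.5-fold), and lower in 1, Shmt2 (-0.92, adjusted p = 0.036; 4 and 1 adjusted over the list alone; camera adjusted p = 0.069). Of 29 chemokine and cytokine genes, Ccl9 was 5.22-fold higher and Cxcl12 3.24-fold lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.4 with an estimated correlation). Apoptosis genes rose in 3 of 35 cases, including Casp12 (17.7-fold; 6 higher and 1 lower adjusted over the list alone), and glycolysis genes fell in 2 of 27 (2 higher and 4 lower adjusted over the list alone).

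Of the clock genes, 4 picked after the data were examined differed between WT liver and all other libraries. In the 2 WT livers Arntl stood at 45.4 and 30 CPM, against 0.874 to 13.7 CPM in the other 8 libraries, Nfil3 at 56.2 and 41.4 against 2.11 to 23.9, Per3 at 3.77 and 8.64 against 24.5 to 64.3, and Tef at 77.1 and 63.3 against 133 to 270. In WT tumours against WT liver 7 of 21 clock genes were higher and 4 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.47). In KO against WT liver none of the 21 passed over all genes (5 higher and 2 lower adjusted over the list alone), and the list did not pass either (camera adjusted p = 0.16; adjusted p = 0.95 with an estimated correlation). The times of day at which the mice were killed are not given in the sources used here.

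Marco separated the genotypes in every library, at 31.6 to 62.4 CPM in the 5 KO libraries and 2.26 to 10.6 CPM in the 5 WT libraries. It passed the test between tumours (adjusted p = 0.0025 in edgeR) and not between livers (adjusted p = 0.12).

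Timm22 and Dennd4a, on chromosomes 11 and 9, varied widely within the groups. Timm22 had 3482 and 8861 counts in WT liver, 567 and 715 in KO liver, 6939, 14363 and 14608 in WT tumours and 23969, 5268 and 13085 in KO tumours, and Dennd4a had 1383 and 3671, 463 and 361, 3010, 6143 and 6602, and 9972, 2850 and 5387. The count table does not show whether these reads come from the transcripts of the 2 genes.

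Reads of weakly expressed genes came in clumps. Genes with a group mean of 10 to 20 counts had no count in 21.5% to 30.2% of libraries, where independent reads would leave at most 0.00064%, and the variance was 26.6 to 34 times the mean for genes with 20 to 500 counts. A hypothesis is that few cDNA molecules were each read many times, which would make the extra dispersion fall with the mean at a slope near -1 on log scales. Differences between animals alone would leave a slope near 0 if they were alike at all levels of expression, which was not tested. The slope was -0.787 over bins from 5 to 500 reads, nearer to the value for few molecules. It argues against animal differences that are alike at all levels as the whole cause. Animal differences that are larger in weakly expressed genes would also give a falling slope, so it does not separate the explanations. Taking all variance as sampling of molecules, the ratio of variance to mean gives 430000 to 520000 molecules per library. Differences between animals would make this figure too low. The ratio also rose with the mean, from 20.8 at 10 to 20 reads to 33.9 at 200 to 500 reads. No biological explanation was tested beyond differences between animals.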
